A study of Mus musculus with 9 samples.

How the data were processed

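RNA of 9 samples from 3 female BALB/c athymic mice, numbered 832, 833 and 834 in the labels, was measured on 9 two-colour Agilent mouse expression arrays. Per the labels' protocols, each mouse gave blood before (day 0) and 10 days after subcutaneous inoculation of Hepa1-6 cells, a mouse hepatoma cell line, and the tumours of day 10 gave a fraction enriched in tumour-infiltrating inflammatory cells (TIC fraction). On every array the sample RNA was labelled with Cy5 and a common reference, blood RNA of an untreated female C57Bl/6 mouse, with Cy3. The dyes were not swapped, so a bias of one dye for a probe stays in the ratio to the reference and leaves the differences between groups only where it is equal on all arrays.

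The authors deposited the scanner tables of the 9 arrays with spot and local background intensity in each channel, processed signal intensity and the log10 ratio of Cy5 over Cy3. Per the file headers, these were made with Agilent Feature Extraction 10.5.1.1, while the submitters' processing notes name version 9.1.3.1. Per the file headers the processed signals were background-subtracted and dye-normalized by a linear and lowess method. The deposited value table of the whole series held the same log10 ratios as the scanner tables. Its scale was log10 and its direction sample over reference. Over all spots, controls included, its columns had a median of 0 on each array. This does not show centring over the tested genes. With these values their median log2 difference was -0.206 between the bloods. It was 0.846 for the TIC fraction against day 10 blood and 0.358 against day 0 blood.

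The analysis started from the mean spot intensity and median local background. Each array had 45018 spots, of which 43379 were not controls, and no spot was saturated. Background was corrected by the normexp method with an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess, with control spots and spots marked as outliers by the scanner software at weight 0. Spots whose local background the scanner software marked as non-uniform, 0 to 103 an array, were set aside before normexp. This choice was made after a first run with all spots had been seen. In that first setting a few spots with very bright local background had spoiled the normexp fit on the day 0 blood array of mouse 834 and the TIC array of mouse 832. The fitted Cy5 background SD on these arrays was 42.42 and 118 intensity units with all spots, and 0.83 and 0.87 without the marked ones. The setting with all spots was kept as an alternative.

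Spots of one probe were averaged, and 213 of 41174 probes with no usable spot on some array were left out. Of all probes, 20153 were well above background in Cy5 on at least 3 of the 9 arrays, and the 19995 of them with values on all arrays were kept. For each gene the probe with the highest mean intensity over all arrays was used, giving 14253 genes. Gene names came from RefSeq accessions of the probes for 23374 probes, from current symbols for 6733 and from synonyms for 2919, through a table of assembly GRCm38.p6 used for names only. The names in the files were kept for 8148 probes. Probe positions are those of the files, on mouse build mm8. Several probes were kept for 4351 genes. For Cd8b1 (TIC fraction against day 10 blood, -3.58) and Itgax (TIC fraction against day 0 blood, 0.61) a second probe passed the threshold in the opposite direction (0.50 and -0.50). Cd8b1 was not well above background on any day 10 blood array, so its value has no reliable sign or size. Other probes of a gene often differed in size from the one used.

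Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with group as the only term and all 9 arrays in the fit, which left 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. For 24 gene lists fixed before the data were examined, camera was run with a preset inter-gene correlation of 0.01 and, as an alternative, with an estimated correlation. Lists with at least 5 measured genes were tested, 23 in all, and the primary granule list had 3. Named genes follow a rule fixed in advance. For each comparison it takes the 10 largest rises and the 10 largest falls among called genes with a gene symbol and the same direction in all 3 mice. It also takes up to 4 members of each list with the smallest p. Where no gene was called it takes the 5 genes with a gene symbol that have the smallest p. Accessions, RIKEN clones and Gm numbers did not count as symbols, so genes without one could have larger changes. A gene not well above background in Cy5 on any array of one group has only a bound there. Bounds were computed from single-channel values after loess and Aquantile normalization, which are open to dye bias. For many of these genes the bound lay above the fold of the fitted log ratio, so that it bounded nothing, and such genes are given in the results with their adjusted p and without a fold.

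Arrays lay on 3 slides. Slide 1 held the TIC array of mouse 832, slide 2 the day 0 arrays of mice 832 and 833 with the TIC arrays of mice 833 and 834, and slide 3 the day 0 array of mouse 834 with the 3 day 10 blood arrays. Day 10 blood and the TIC fraction therefore shared no slide. The mouse numbers were taken as those of animals, so that arrays with one number are paired. Deviations from the group means of the 2 blood arrays of one mouse correlated across genes at 0.186, 0.345 and 0.243 for mice 832, 833 and 834, while those of TIC and blood arrays of one mouse lay between -0.06 and 0.06. The planned fit had no mouse block, and the fit with it was an alternative.

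The scripts were tested on simulated data in which the 14253 genes kept their own means and spreads. For blood at day 10 against day 0, genes changed by 1 on the log2 scale were called in 68% of cases and those changed by 2 in 92%. That simulation also held genes changed by 4, and 145 genes were called in all, which eases the Benjamini-Hochberg threshold. These shares therefore do not carry over to a comparison with few called genes. Alternatives covered background correction, normalization, filters on dim probes, the choice of probe, the arrays in the fit, array weights, mouse and slide blocks, and leaving out each array in turn. Having 3 arrays in each group limits the precision, as does the share of spots above background given below.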

Results

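The series profiled blood of 3 athymic mice, which lack a thymus and so most T cells, before and 10 days after inoculation of Hepa1-6 hepatoma cells, together with a cell fraction of the tumours enriched in infiltrating inflammatory cells. Each of the 3 groups (day 0 blood, day 10 blood and day 10 TIC fraction) held 1 array from each of the 3 mice. The labels describe a design of 2 conditions and state no further question. Values are log2 ratios to the common reference blood RNA or differences between them, with the SE of the limma fit. This SE rests on 1 spread for all 3 groups, so for the bloods it also takes in the TIC arrays. P-values are limma's after Benjamini-Hochberg adjustment unless named otherwise.

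Sample RNA was dimmest on the day 10 blood arrays. The share of spots well above background in Cy5 was 31.2% ± 6.39 (SD, n = 3) in day 0 blood, 17.7% ± 3.41 in day 10 blood and 52% ± 3.5 in the TIC fraction. In the Cy3 reference it lay between 40.2% and 50.4% on all 9 arrays. Across the tested genes, the first principal component held 88.2% of the variance and parted the TIC arrays from the blood arrays. Replicate arrays correlated across genes at 0.79 to 0.82 in day 0 blood and 0.80 to 0.88 in day 10 blood. Among the TIC arrays, mice 832 and 834 correlated at 0.99, and mouse 833 stood apart from them at 0.89 and 0.90.

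**Figure D1:**
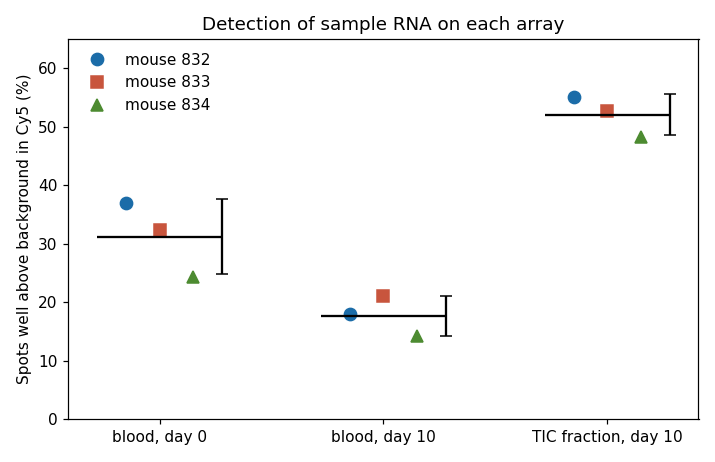
Percentage of non-control spots well above background in the Cy5 channel (y axis) for each array, by group (x axis). Symbols mark the mouse, horizontal lines the group mean and error bars the SD (n = 3). The day 10 blood arrays lie between 14.2% and 21%, below all day 0 and TIC arrays.

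The T cell list served as a check of the ratio's direction, since the reference mouse has a thymus. On each of the 3 day 0 arrays 19 of 20 T cell genes well above background in the reference lay below 0, and the array medians were -0.64, -0.75 and -0.38. On the TIC arrays all 20 lay below 0, with medians of -2.11, -1.98 and -1.74. On the day 10 blood arrays the shift was smaller, with 16, 18 and 14 of 20 below 0 and medians of -0.35, -0.32 and -0.18. This order depended on the normalization, since with median centring the group means were -1.18 (day 0), -1.38 (day 10) and -1.03 (TIC).

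Blood of day 10 was compared with blood of day 0 to see how circulating cells changed after inoculation. Genes of red cells were higher and genes of B cells lower at day 10 in each of the 3 mice. In the planned fit, however, no single gene passed the threshold among all genes tested, a count that other fits changed (below). The erythroid list had a median difference of 1.02, with medians of 0.82, 1.44 and 1.22 in mice 832, 833 and 834. Of its 23 measured genes, 17 were higher when adjusted over the list alone. Tspo2, a translocator protein of erythroid cells, was 2.22 ± 0.30 higher (adjusted p = 0.0582), Slc4a1, the band 3 anion exchanger, 2.39 ± 0.41 (adjusted p = 0.0663) and Ank1, the erythrocyte ankyrin, 1.99 ± 0.32. The B cell list had a median of -0.94, and 14 of its 18 genes were lower when adjusted over the list alone. Ms4a1, which encodes CD20, differed by -2.00 ± 0.30, Vpreb3 by -1.73 ± 0.22 and Pou2af1, a B cell coactivator, by -1.84 ± 0.30. The MHC class II list, which B cells also express, had a median of -0.81 with 7 of 9 genes lower over the list alone, among them H2-Ab1 (-1.81 ± 0.29) and H2-Aa (-1.75 ± 0.33), whose other probes reached -0.50 and -0.18. In camera with the preset correlation the adjusted p was 7.36e-18 for the erythroid list, 1.43e-15 for the B cell list and 1.68e-08 for the MHC class II list. With an estimated correlation the adjusted p was 0.175, 0.0649 and 0.0649.

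Smaller shifts were measured in 4 more lists. The platelet list had a median of 0.71 (adjusted p = 1.17e-05 preset, adjusted p = 0.376 with an estimated correlation) with 4 of 11 genes higher over the list alone, and the platelet chemokine gene Ppbp differed by 1.22 ± 0.27. The neutrophil list had a median of -0.48 (adjusted p = 2.95e-05 preset, adjusted p = 0.182 estimated) with 2 of 18 genes lower over the list alone, including Pglyrp1 at -1.43 ± 0.27. Its call was also lost with Agilent processed signals, the deposited log ratio, Cy5 alone and slide as a block. The T cell and fibroblast lists had medians of 0.54 and 0.57 (adjusted p = 1.49e-07 and 0.000159 preset, adjusted p = 0.235 and 0.175 estimated). In the Cy5 channel alone these medians were 0.17 and 0.08, and 7 T cell and 7 fibroblast genes were not well above background on any day 10 blood array. Among interferon-stimulated genes the list median was -0.07, while 5 of 24 were higher over the list alone and 1 lower. Isg15 differed by 1.77 ± 0.33 and Irf7 by 0.94 ± 0.17 (adjusted p = 0.0702 for each over all genes). Without loess, when arrays were only centred on their medians, the medians of the erythroid, T cell, fibroblast and platelet lists were -0.07, -0.10, -0.01 and -0.40, against a median of all genes of -0.18. The erythroid list stayed higher than other genes in camera under that centring.

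Over all genes, limma called 0 of 14253 genes between the 2 bloods, with 2104 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0514. The 5 named genes with the smallest p did not pass. They were Dnajb2 (1.41 ± 0.15), a co-chaperone, Cmas (2.05 ± 0.23), an enzyme of sialic acid activation, the histone genes H2bc4 (1.38 ± 0.16) and H2bc14 (0.91 ± 0.11), and Metap2 (2.11 ± 0.25), a methionine aminopeptidase. Other probes were at -0.13 for H2bc4 and between 0.42 and 2.26 for Metap2. The Tspo2 probe lies on chromosome 17 at 47914049 to 47914108 and that of Ms4a1 on chromosome 19 at 11317922 to 11317981 (build mm8). The count of 0 did not hold in other fits. With the mouse as a block 32 genes were called, with only the 2 blood groups in the fit 747, and with the deposited log ratio 757. With slide as a block the count was 0, but that difference rests on the 1 day 0 array of slide 3, which has no spread of its own. Within slide 3, on 3 day 10 arrays and this 1 day 0 array, the medians of the fitted differences were 0.88 (erythroid), -1.18 (B cell) and -1.23 (MHC class II).

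**Figure D2:**
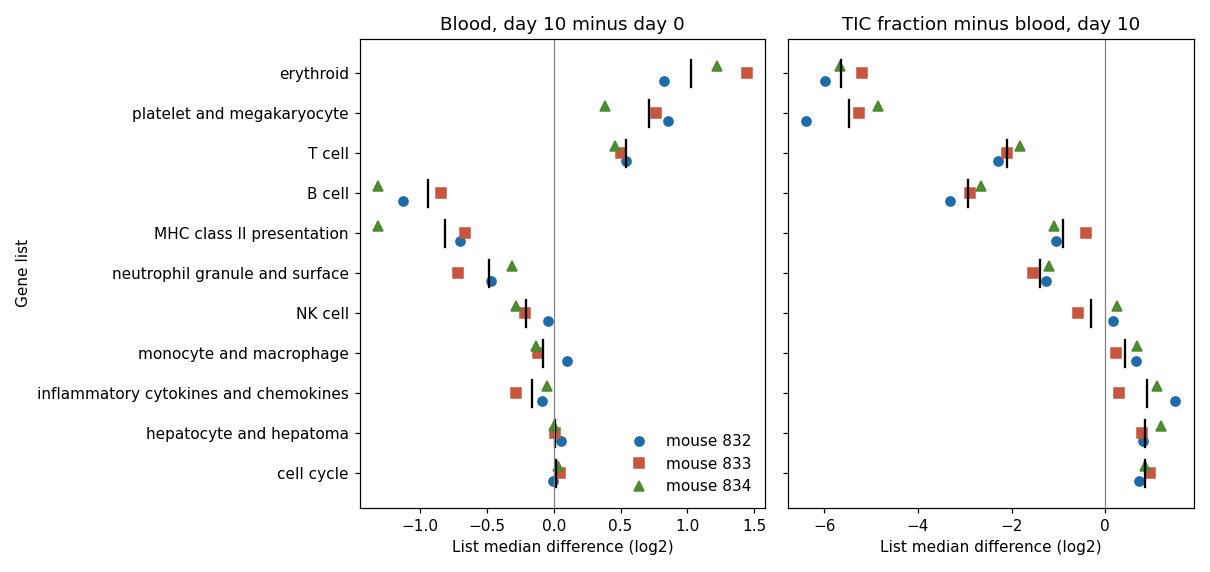
Median log2 difference of the genes of 11 lists (x axis, log2) in blood at day 10 minus day 0 (left) and in the TIC fraction minus blood at day 10 (right). Symbols give the median in each mouse and the black line the median of the fitted differences. In the left panel the erythroid medians lie between 0.82 and 1.44 and the B cell medians between -1.31 and -0.84.

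The TIC fraction was compared with blood of the same day, and differed from it across much of the transcriptome. Hepatoma and liver genes and cell cycle genes were higher in the fraction, and erythroid, platelet, B cell and neutrophil genes were lower. Of 14253 genes, 4908 were higher and 4724 lower, and 9506 of the 9632 called genes had one direction in all 3 mice. Among the called genes, 4727 were not well above background on any array of one group.

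Of 20 hepatocyte and hepatoma genes, 16 rose and 2 fell (list median 0.84). Camera gave an adjusted p of 0.000928 with the preset correlation and an adjusted p of 0.171 with an estimated one. The list was tested in 26 alternatives, against 28 for the cell cycle list, since stricter filters on dim probes left under 5 of its genes. A gene could also be kept through its signal on the 3 TIC arrays alone. Afp, the fetal liver protein alpha-fetoprotein, rose by 5.35 ± 0.28 on the log2 scale (adjusted p = 1.72e-06), well above background on 1 of 3 day 10 blood arrays. Alb, which encodes albumin (adjusted p = 2.43e-06), and Igfbp1, a liver-secreted binding protein (adjusted p = 1.03e-06), were higher and not well above background in day 10 blood. Fgb, a fibrinogen chain gene, rose by 2.66 ± 0.14 (2 of 3 day 10 blood arrays above background), while Ahsg fell by 3.51 on the log2 scale (SE 0.23). The Afp probe lies on chromosome 5 at 91583955 to 91584014 and the Alb probe on the same chromosome at 91547772 to 91547831. Of 27 cell cycle genes 19 rose and 2 fell (median 0.86, adjusted p = 0.000143 preset, adjusted p = 0.183 estimated), and the list lost its call when only genes above background on all 9 arrays were kept. Cdc20, an activator of the anaphase-promoting complex, rose by 2.59 ± 0.14 (1 of 3 day 10 blood arrays above background) and Birc5, which encodes survivin, by 2.55 ± 0.24. Plk1, a mitotic kinase gene (adjusted p = 5.31e-06), and Psrc1 (adjusted p = 2.34e-07) were higher and not well above background in day 10 blood. Other rises were those of Nme2 (4.53 ± 0.20), Npm1, the nucleophosmin gene (4.49 ± 0.34), and Prdx1, a peroxiredoxin gene (4.11 ± 0.41).

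Of 23 cytokine and chemokine genes 14 rose and 3 fell (median 0.89, adjusted p = 0.0288 preset, adjusted p = 0.548 estimated). The list lost its call in 9 of 28 alternatives. These were the estimated correlation, median centring, Cy5 alone, the 3 filters on dim probes that were stricter, the slide block with and without the mouse block, and leaving out the TIC array of mouse 832. Ccl2, a monocyte attractant (adjusted p = 8.83e-05), Cxcl10 (adjusted p = 4.45e-05) and Cxcl3, a neutrophil attractant (adjusted p = 0.000119), were higher and not well above background in day 10 blood, whereas Csf1 fell by 4.49 (SE 0.36). The list median was 0.29 in mouse 833 and 1.49 and 1.11 in mice 832 and 834. The macrophage list did not pass as a list (adjusted p = 0.108), with 9 of 20 genes higher and 2 lower. C1qc and C1qa, chains of complement C1q, and Aif1 were higher (adjusted p = 3.91e-05, 0.000862 and 3.41e-06) and not well above background in day 10 blood. Of the genes of alternative activation, Gpnmb and Fn1 were higher (adjusted p = 3.12e-06 and 7.76e-06) and likewise not above background in that blood. Cd36 and Chil3 were lower (-4.49 and -2.68), and when arrays were only centred on their medians they were at 0.28 and 1.17, below the median of all genes of 1.38. The list of these genes had 10 of 18 higher and 5 lower (median 0.68, adjusted p = 0.168). In mouse 833 the medians of this list and of the macrophage list were 0.23 and 0.22, against 1.01 and 0.66 in mouse 832 and 0.90 and 0.67 in mouse 834. Among other lists that did not pass, members went both ways. Of 15 immediate-early genes 8 were higher and 3 lower, with Fos at 2.75 ± 0.26 (1 of 3 day 10 blood arrays above background), and of 8 heat shock genes 4 were higher, among them Hspd1 (2.36 ± 0.16), and 1 lower. Of 19 hypoxia and glycolysis genes 9 were higher, among them Tpi1 (2.62 ± 0.14), and 3 lower, among them Car9 (-2.71 ± 0.22). Of 10 matrix protease genes 7 were higher, among them Ctsl (2.66 ± 0.45), and 1 lower, Ctsb (-4.95 ± 0.74), whose second probe was at -0.10. Under median centring Car9 and Ctsb were at 0.41 and 1.44, against the median of all genes of 1.38.

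Among lower genes, 22 of 23 erythroid genes fell (median -5.63), as did all 11 platelet genes (-5.48), all 18 B cell genes (-2.93) and 12 of 18 neutrophil genes (-1.40). The adjusted p with the preset correlation was 4.35e-10, 2.83e-07, 1.58e-07 and 0.000928 in this order. With an estimated correlation the adjusted p was 0.183 for the B cell list and 0.252 for each of the others. The neutrophil list also lost its call when only genes above background on all 9 arrays were kept. Among the falls were Hbb-y, a beta-like globin gene (-11.81 ± 0.24, adjusted p = 1.4e-07), Alas2, the first enzyme of erythroid haem synthesis (-11.47 ± 0.61), Fech, its last enzyme (-11.16 ± 0.48), and Ppbp (-9.57 ± 0.27). In the Cy5 channel alone the same differences were -7.45, -6.52, -6.95 and -6.15, so the size of the fold depended on the normalization. S100a8 and S100a9, which encode the neutrophil protein calprotectin, were lower by ratio (-4.93 and -5.52), and when arrays were only centred on their medians they were at 0.94 and 1.68, against the median of all genes of 1.38. Rsad2, an interferon-stimulated gene, fell by 10.81 (SE 0.51), and 14 of 24 interferon-stimulated genes fell with 5 rising (adjusted p = 0.0648 for the list). The T cell list was lower by ratio (median -2.10, adjusted p = 9.67e-06 preset, adjusted p = 0.252 estimated). However, 7 of its 14 genes were not well above background on any day 10 blood array, so the size of this difference is not supported, and no call was made in Cy5 alone (median -0.42, adjusted p = 0.143). When arrays were only centred on their medians, 95.7% of the called genes were higher in the TIC fraction instead of 51%, and the median of all genes was 1.38. Under that centring the medians were -0.90 for erythroid, -1.61 for platelet and -0.36 for B cell genes, while those of the T cell (0.34) and neutrophil (0.72) lists were above 0 but below the median of all genes. The hepatocyte and hepatoma list then had a median of 1.59 and was no longer called (adjusted p = 0.325), and the cell cycle list stayed higher (3.05). The deposited log ratio gave 63.3% higher, with a median of all genes of 0.85. The share was 23.4% with genes above background in Cy5 on all 9 arrays, 35% with slide as a block and 19.3% with mouse and slide as blocks. The groups shared no slide, and with slide as a block, where the difference runs through the day 0 arrays of slides 2 and 3, 4274 genes were called, 4210 of them among the 9632.

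The TIC fraction was also compared with blood before inoculation, for which 2 arrays of each group shared a slide. Here 4524 genes were higher and 4796 lower, with 2489 of the 9320 not well above background on any array of one group. The lists followed the comparison with day 10 blood in the direction of erythroid (median -4.18), platelet (-5.05), B cell (-4.09), T cell (-1.71) and neutrophil (-1.96) genes. The T cell list had no call in Cy5 alone (median -0.13, adjusted p = 0.249). Hepatocyte and hepatoma genes rose in 17 of 20 cases (median 0.81, adjusted p = 0.000201 preset, adjusted p = 0.0945 estimated) and cell cycle genes in 19 of 27 (median 0.93, adjusted p = 2.02e-06 preset, adjusted p = 0.0945 estimated). The MHC class II list was lower (median -1.49, adjusted p = 0.00237 preset, adjusted p = 0.219 estimated) with 7 of 9 genes falling, among them H2-Oa (-3.71 ± 0.13) and Ciita, the class II transactivator gene (-2.65 ± 0.31). The interferon-stimulated list was lower as well (median -0.81, adjusted p = 0.0286 preset, adjusted p = 0.219 estimated), with 15 of 24 genes falling. Its call was also lost with median centring and when the day 0 array of mouse 833 was left out. The cytokine and chemokine list was not called here (median 0.99, adjusted p = 0.0516 preset, adjusted p = 0.619 estimated). Its median was -0.05 in mouse 833 and 1.70 and 1.16 in mice 832 and 834. The adjusted p with the preset correlation was 5.12e-09 for erythroid, 3.81e-07 for platelet, 3.18e-09 for B cell, 0.000112 for T cell and 2.68e-05 for neutrophil genes. With an estimated correlation the adjusted p was 0.241, 0.219, 0.112, 0.241 and 0.217.

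Single genes with large differences from day 0 blood included Afp (5.32 ± 0.28), Prdx1 (4.07 ± 0.41) and Ccl8, a chemokine gene not well above background in day 0 blood (adjusted p = 0.000253). Dcn, which encodes the matrix proteoglycan decorin, rose by 3.36 ± 0.17 (1 of 3 day 0 arrays above background) on one probe and was at 0.47 on the other. The fibroblast list had 3 genes higher and 6 lower of 12 and was not called (camera adjusted p = 0.437 with the preset correlation). Its median ran from -0.67 to 1.08 over all settings, so it has no settled direction. Mmp13, a collagenase gene, was higher (adjusted p = 0.000135) and not well above background in day 0 blood. Hbb-y (-10.83 ± 0.24), Alas2 (-10.55 ± 0.61) and Ms4a1 (-7.47 ± 0.30) were lower. Within slide 2, on 2 arrays of each group, 3489 genes were called, 3483 of them among the 9320, and list medians were -3.62 for erythroid, -3.77 for B cell, -1.40 for T cell, 0.80 for hepatocyte and hepatoma and 1.02 for cell cycle genes. When arrays were only centred on their medians, 92% of called genes were higher instead of 48.5%, with a median of all genes of 1.16, and the medians of the T cell, MHC class II and interferon-stimulated lists were 0.21, 1.37 and 1.30.

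Whether blood at day 10 had moved in the direction of the TIC fraction was asked over all genes. The differences of day 10 blood and of the TIC fraction from day 0 blood correlated across genes at -0.37, and genes are not independent replicates. Unchanged groups set against the same day 0 arrays gave a correlation of 0.50 in 100 simulations, which took all arrays as independent and left out the pairing by mouse. In them the TIC fraction was unchanged as well, unlike in the data. The 0.50 is therefore no yardstick for -0.37, and only the covariances can be set side by side. The covariance was -0.20 against 0.03 simulated, a difference of -0.22. No gene was called in both comparisons in the same direction, and the simulated overlap and that of independent lists were also 0, since no gene was called between the bloods. The day 0 group of 3 arrays was too small to be split.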

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

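All 9 arrays had dim Cy5 signal for many spots, and this limits blood most. The settings that kept all spots in normexp, kept genes above background in both channels on all 9 arrays, used 2 groups with the mouse block or stayed within 1 slide were added after the files had been seen, the first of them after a first run's results. Series matrix values equalled the deposited log ratio, and Aquantile left the ratios as they were, so neither is a separate test. Fewer genes (3897 and 3870) were tested under the strict filters. With only the 2 groups compared, the fitted differences were those of the planned fit. Only the estimate of the spread and its residual degrees of freedom (4 instead of 6) changed there. For the bloods, the planned estimate also took in the TIC arrays. Other causes of the changes below were not tested.

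For blood at day 10 against day 0, 0 genes became 9 with Agilent processed signals, 757 with the deposited log ratio, 550 with Cy5 alone, 147 with genes above background in Cy5 on all 9 arrays (147 also with both channels), 12 with all probes, 747 with only the 2 groups, 1284 with array weights, 32 with the replicate block, 15 with slide as a random block, 1733 with 2 groups and the replicate block and 576 within slide 3, where 3 day 10 arrays are set against 1 day 0 array without spread, so this count carries little. Leaving out 1 blood array gave 0 to 18, the 18 without the day 0 array of mouse 834. An array was left out only for comparisons that included its group, so no TIC array was left out here. Kept background spots gave 0, 9119 and 8684 genes in the order of the report, on the same genes. For TIC against day 10 blood, 9632 became 2956 (above background in Cy5 on all arrays), 2944 (both channels), 4274 (slide block) and 1110 (replicate block and slide block). Leaving out 1 array gave 8326 to 10945. For TIC against day 0 blood, 9320 became 2910, 2900, 4432 (replicate block and slide block) and 3489 (within slide 2), with 8062 to 10798 on leaving out 1 array. The replicate block alone gave 9435 and 9102 genes and changed no list call. Median centring gave 10737 and 10248 genes, but these were often other genes or had the other sign. Against day 10 blood, 4572 of the 9632 calls were lost or changed sign, 3295 of them by sign. Against day 0 blood it was 4244 of the 9320, 2879 of them by sign. The direction of many calls thus depended on the loess step. The shared count became 3 with processed signals, 159 with the deposited log ratio, 141 with Cy5 alone, 28 with either strict filter, 5 with all probes, 402 with array weights, 4 with the replicate block and 4 with slide as a random block, with 0 to 14 on leaving out 1 day 0 array (the other arrays were not left out for this). The correlation became -0.20 with processed signals, -0.21 with the deposited log ratio, -0.24 with Cy5 alone and -0.15 with both blocks, and ran from -0.38 to -0.30 on leaving out 1 day 0 array. The mean T cell value of day 0 blood against the reference, -0.59, became -2.58 with processed signals, -2.66 with the deposited log ratio and -1.18 with median centring.

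Of the called lists, none held with an estimated correlation. Apart from that, B cell and erythroid lists kept their call in all alternatives of all 3 comparisons. With the estimated correlation counted, the cytokine list lost its call against day 10 blood in 9 of 28 alternatives, the neutrophil list in blood in 7 of 29 (Cy5 alone and slide as a fixed block among them), the fibroblast list in blood in 4 of 27 and the MHC class II list against day 0 blood in 4 of 29. The cell cycle and neutrophil lists lost it against day 10 blood with both strict filters, and the interferon-stimulated list against day 0 blood with median centring and without the day 0 array of mouse 833. The T cell list lost it with median centring and Cy5 alone in each comparison, and the hepatocyte and hepatoma list with median centring against both bloods. Stricter filters on dim probes left too few genes of these lists for a test, so no call was kept or lost there. Median centring turned the platelet list in blood to -0.40, where the median of all genes was -0.18. It moved the median of all genes to 1.38 (TIC against day 10 blood) and 1.16 (against day 0 blood), so a gene under these values still lay below most others. Cd6, Cd8b1, Col1a1, Eng, Flt1, H2-DMb2, Hspb1, Krt14 and Plvap were not well above background on any day 10 blood array, so their values against that blood, in this and the next settings, have no reliable sign or size. The sign changed for these genes, TIC against day 10 blood: Car9 0.41, Ccr7 0.19, Cd36 0.28, Cd3d 0.55, Cd6 0.24, Cd8b1 0.11, Chil3 1.17, Ciita 1.29, Cma1 1.16, Col1a1 0.79, Csf3r 0.25, Ctsb 1.44, Ctsg 1.15, Eng 0.0923, Flt1 0.72, H2-DMa 2.08, H2-DMb2 0.40, H2-Oa 0.24, Hdc 0.22, Hp 1.11, Hspb1 0.70, Ifit1 0.55, Il2rb 1.34, Irf7 0.47, Isg15 1.22, Klrb1c 0.16, Krt14 1.87, Krt5 2.40, Lgals9 2.17, Plvap 0.70, S100a8 0.94, S100a9 1.68, Tbx21 0.57, Xcr1 1.34. Against day 0 blood it changed for Car9 0.15, Cd244a 1.20, Cd274 0.71, Cd36 0.45, Cd3d 0.25, Chil3 0.0747, Cma1 0.53, Flt1 0.55, H2-Ab1 2.53, Ifit1 0.50, Irf7 0.30, Krt14 1.40, Krt5 1.76, Lat 0.0402, Lck 0.17, Nr4a1 2.26, Plvap 0.68, S100a9 0.13, Tbx21 0.12. Cy5 alone turned Col1a1 0.0619, Flt1 0.28, H2-DMa 0.55, Krt14 0.29, Lgals9 0.0263 against day 10 blood and Siglecf -0.0288 against day 0 blood. The deposited log ratio turned Flt1 0.0358, H2-DMa 0.39, Krt14 0.32, Lgals9 0.29 against day 10 blood. The second probe of Itgax gave -0.50 against day 0 blood. Over all alternatives, lists kept camera's direction and stayed called or not called in 577 of 646 cases for blood. For TIC against day 10 blood it was 566 of 623, and against day 0 blood 577 of 646. That direction is relative to other genes, and medians could change sign: the NK cell list counted as kept in 29 of 29 against day 0 blood, with medians from -1.37 to 1.2. Named genes kept their sign and stayed called or not called in 2313 of 2707, 2692 of 2898 and 2853 of 3006.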

Other observations

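The tests of dim signal, of diluted leukocyte RNA, of tumour cells and of normalization below were chosen after the results they bear on had been seen, and those of slide and of the splits of the arrays before.

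Several lists had no call in blood and small medians. Monocyte and macrophage genes had a median of -0.08, NK cell genes -0.20, hepatocyte and hepatoma genes 0.01, endothelial genes 0.13, hypoxia and glycolysis genes -0.03, immediate-early genes -0.16, heat shock genes 0.03, immune checkpoint genes 0.04 and matrix protease genes 0.12. Tumour-associated macrophage genes had a median of 0.02, dendritic cell genes 0.01, mast cell, basophil and eosinophil genes -0.11, skin, fat and muscle genes 0.18, cytokine genes -0.16 and cell cycle genes 0.01. The 3 measured primary granule genes had a median of -0.03. Within the cell cycle list Ccna2 and Mki67, a proliferation marker, differed by 1.20 ± 0.21 and 1.17 ± 0.24 (limma adjusted p = 0.0664 and 0.0921). In the TIC fraction against day 10 blood, medians without a call were -0.30 for NK cell, 0.03 for dendritic cell, -0.91 for MHC class II, -0.07 for mast cell, basophil and eosinophil, -1.15 for fibroblast, -0.13 for endothelial, -1.17 for skin, fat and muscle and 0.44 for immune checkpoint genes.

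Erythroid genes were higher and B cell genes lower in day 10 blood. Over the 18 erythroid and 11 B cell genes well above background on all 6 blood arrays, the medians in Cy5 alone were 1.04 and -1.35. The difference was thus not confined to dim genes. However, these Cy5 values were quantile-normalized, which gives dim and bright arrays the same distribution, so an effect of dim Cy5 signal stays open. With median centring the erythroid list median was -0.07, against -0.18 for all genes. The B cell list median ran from -1.89 to -0.82 over all settings. A mere dilution of all leukocyte RNA stays open. The B cell median lay below the monocyte median by -1.05 ± 0.281 (mean and SD over 3 mice), but this took all monocyte genes, also dim ones. Neutrophil genes fell too, with medians of -0.47, -0.72 and -0.31 in mice 832, 833 and 834. The B cell medians were -1.13, -0.84 and -1.31. Slide stays open: within slide 3 the middle values of the list medians of the single day 10 arrays were 0.723 and -1.16, but against 1 day 0 array. The tumour, the time between the bleeds and the first bleed itself, which may raise young red cells, cannot be parted by this design.

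T cell and fibroblast genes were also higher in day 10 blood by log ratio, with medians of 0.538 and 0.57. In the Cy5 channel alone the medians were 0.171 and 0.0785. Dim Cy5 signal that the loess curve lifts is a candidate explanation for most of this difference. No biological explanation was tested.

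Hepatocyte and hepatoma genes were higher in the TIC fraction, 16 of 20 against day 10 blood and 17 of 20 against day 0 blood. The normalization was argued against as the cause of the direction in 2 settings only. The list medians against both bloods, in Cy5 alone and in the deposited log ratio, ran from 0.656 to 3.12. They were set against 0, while the medians of all genes were 0.215 and 0.113 in Cy5 alone and 0.846 and 0.358 in the deposited log ratio. In both settings the list kept its camera call with the preset correlation. The list call did end when arrays were only centred on their medians. There the list medians were 1.59 and 1.56 (adjusted p = 0.325 and 0.139), while the medians of all genes were 1.38 and 1.16. Tumour cells left in the fraction may account for the 16 and 17 rises, and Afp and Alb, abundant products of such cells, were among the rises. The list holds genes that liver also expresses, and uptake of such RNA by other cells was not tested.

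Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. For TIC against day 10 blood the real split gave 9632 genes and the highest other 0, with 1 split as large. Against day 0 blood it gave 9320 and the highest other 0, also with 1 split as large. Each other split put TIC and blood arrays on both sides, and the component that parts them held 88.2% of the variance. Few or no calls there were thus fixed in advance, and the contrast with 0 says nothing about chance. For the bloods all 10 splits gave 0.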
